A study of Mus musculus with 4 samples.

How the data were processed

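Bhlhe40 ChIP-seq was analysed from the peak files that the authors deposited for 2 ChIP libraries, 1 from naive and 1 from IL-4c-treated mice. Large peritoneal macrophages were sorted from pooled mice, per the series design. The labels also describe 1 input DNA library per condition, for which no files were used here. The antibody was an anti-Dec1 antibody, the same lot in both ChIP libraries, per the labels.

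The submitters' processing notes name FastQC 0.11.3, Bowtie 1.1.1, MACS 1.4, deepTools 2.5.3, ChIPseeker 1.14.1 and the mm10 build. The settings of each tool, and how the input libraries entered the peak calls, are not given in the sources used here. For each ChIP library the authors deposited an interval list and an annotated table of peaks called in that library alone. The tag count of a peak is the whole-number count of tags in it that the authors deposited, not scaled to the size of the library. The score of a peak is the value the authors deposited under a damaged column name. It was read as 10 times the negative log10 of the caller's p, because its minimum is about 50, which corresponds to a p of 1.00e-05. The fold enrichment is the ratio deposited by the authors for each peak. The false discovery rate is a percent, per the file headers and its steps along the ranked peaks, and reached at most 0.4% in the naive and 0.1% in the IL-4c table. The annotation gives each peak a genomic class, a nearest gene and a distance to its TSS.

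The annotated tables held 2245 naive and 5011 IL-4c peaks, and the interval lists 2309 and 5299. All table peaks had a fold of at least 5.03 (naive) and 5.01 (IL-4c), and none lay on an unplaced contig. The tables were used throughout, except where 5 naive peaks without a counterpart were set against the IL-4c interval list and in 1 alternative. The peaks found only in the interval lists are described in the closing section. Starts are given 1-based, as in the tables. Gene symbols turned into dates by spreadsheet software, on 4 naive and 11 IL-4c peaks, were restored from the gene name column. Older symbols, on 40 and 88 peaks, were matched to current ones through a RefSeq gene table of the GRCm38.p6 assembly, which is mm10. On 1 naive and 5 IL-4c peaks the symbol had no match. Tmem55b is Pip4p1 in that table.

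Each library formed its own group, and no test between conditions was made. Shares of peaks carry exact 95% Clopper-Pearson intervals. Peaks were called shared at an overlap of at least 1 bp. Chance overlap came from 1000 shuffles of the peaks within their chromosomes, between 3 Mb and the last gene end, because chromosome lengths were not used here. Promoter shares of shared and unshared peaks were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over both lists.

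Genes were the protein-coding genes of the RefSeq table, 21887 in number, and a gene was called bound when the annotation assigned it a peak. For 21 gene lists the share of bound genes was set against 10000 random lists of the same size, drawn from protein-coding genes matched in 10 divisions of gene territory, which is a permutation test of list membership within each division. The plan was to measure territory between neighbouring TSSs, but the gene table gives no strand, so that distances between neighbouring gene centres were used. Two-sided p-values from the random lists were adjusted by the Benjamini-Hochberg method over the 21 lists, and the smallest p they can give is 2.00e-04. For the comparison of the libraries, genes bound in both were counted against genes bound in 1 by Fisher's exact test, two-sided, for each list against all other bound genes. All of these p-values describe the 2 peak lists and not the conditions.

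The gene lists were clock and PAR-bZIP, large Maf and self-renewal, large peritoneal macrophage, small peritoneal macrophage, pan-macrophage, IL-4 response, cell cycle, lysosome and autophagy, glycolysis and hypoxia, mitochondrial respiration, ribosome biogenesis, lipid and sterol metabolism, inflammatory cytokine, AP-1 and immediate early, and markers of B cells, T cells, mast cells and granulocytes, mesothelium and fibroblasts, neurons, hepatocytes and skeletal muscle. From these, 1 gene was left out for lack of a protein-coding match. Some genes stood in more than 1 list. The genes named were Bhlhe40, Bhlhe41, Maf, Gata6, Il10 and Myc in any case, the genes of the 10 highest scoring peaks of each list, the genes of the 5 highest scoring peaks found in 1 list only, up to 4 bound members of each gene list with the highest scoring peak of either library, and up to 5 IL-4 response genes per library with a peak in 1 library only. Unnamed predicted genes were passed over, and some genes that the rule takes are not reported here. The other bound clock genes and Flcn were named outside this rule, after their values were seen. The gene lists, this rule, the tests and the other settings were fixed before the data were examined.

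Those settings were a score of at least 100, the same number of top peaks from each list, a promoter limit of 1 kb, a reciprocal overlap of 50%, summits within 200 bp, peaks within 50 kb of the TSS, promoter peaks alone and unmatched random lists. Using every peak of the interval lists, and counting a gene as bound in both where its peak overlapped a peak given to another gene, were added after the data were seen. Motif content of peaks and E-box content by score were planned, with 29 motifs, and were not run because no genome sequence was used here.

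Both procedures were tested on simulated data. Of 800 naive peaks placed on IL-4c peaks a mean of 804.4 were found over 20 draws, chance overlaps included. Among 1000 simulated list tests with no effect the matched random lists made 4 calls and the unmatched lists 51. Bound genes were drawn there in proportion to territory, and the lists came from genes of larger territory. The simulation thus rested on the variable used for matching, and its number of bound genes was that of neither library. Its rates need not hold for the deposited peaks. Simulated lists of 20 genes were recovered in 2% of cases at 2 times the chance count and in 100% at 4 times. The analysis used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.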

Results

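Binding of the transcription factor Bhlhe40 (also called Dec1) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in large peritoneal macrophages, the resident macrophage population of the mouse peritoneal cavity. Bhlhe40 is a basic helix-loop-helix repressor of the circadian clock family. Cells were sorted from pooled C57BL/6 mice that were left untreated (naive) or injected with IL-4c on days 0 and 2 and killed on day 4. The series held 4 libraries, with 1 Bhlhe40 ChIP library and 1 input DNA library per condition, and there were no replicates. Every comparison below is therefore between these 2 ChIP libraries and not between the conditions. Total reads per library are not given in the tables used here, so the depth behind a peak is known only as its tag count, with a median of 19 tags per peak in the naive library and 50 in the IL-4c library. Intervals are exact 95% binomial intervals over peaks or genes, and they cover counting error only. Coordinates are on the mm10 build.

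The first question was where Bhlhe40 was bound in resting macrophages and in macrophages of IL-4c-treated mice. In the naive library the highest scoring peak lay at the promoter of Polr3a, which encodes the largest subunit of RNA polymerase III (chromosome 14, 24486660 to 24487321, 235 tags, score 2678). In the IL-4c library the highest listed score was at the promoter of the zinc finger gene Zfp292 (chromosome 4, 34882336 to 34883483, 385 tags, score 3204), while 6 further peaks all carried a score of exactly 3100, so that the order among these 7 peaks is not resolved. The peaks at Polr3a, at Btaf1, a regulator of TATA-binding protein, and at a site 56677 bp from the transcription start site (TSS) of Rbx1, a subunit of cullin ubiquitin ligases, were among the 10 highest in both lists. The scores and fold enrichments are the authors' own per-peak values and are ranked within a list. Exceptions are the naming of gene list members, the matching of bound genes on score and limits applied alike to both lists.

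The naive list also had among its 10 highest peaks the promoters of Foxo3, a forkhead transcription factor (237 tags), Dpy19l3 (158 tags), Usp53 (144 tags) and Cstf1 (163 tags), and an exon of the carbonic anhydrase gene Car3 (216 tags). The remaining places in that list were taken by 2 intergenic peaks on chromosome 2 that the annotation assigned to Lrrc4c, whose TSS lay 1198515 and 1194561 bp away. These 2 peaks held 994 and 797 tags at fold enrichments of only 5.79 and 5.06, against 107 at Polr3a. In the IL-4c list the other high peaks lay at promoters of Zfp36, which encodes an mRNA decay factor (414 tags), Aurka, a mitotic kinase (436 tags), Tmem55b, a lysosomal membrane protein (581 tags), Bnip3, a mitophagy receptor (386 tags), Ciart, a repressor of the circadian clock (397 tags), and Washc1 (363 tags). The site given to Cstf1 in the naive list and the site given to Aurka in the IL-4c list overlapped, at 172370683 to 172371312 and 172370355 to 172371471 on chromosome 2.

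The naive list had 2245 annotated peaks and the IL-4c list 5011, which is 2.23 times as many. The IL-4c peaks were also wider, with a median of 911 bp against 299 bp, and together covered 4715 kb against 734.6 kb of the genome. With 1 library per condition no test of the number of peaks was possible. A score of at least 100 left 985 and 2895 peaks.

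In both libraries the largest class was the promoter. Peaks within 3 kb of a TSS made up 55.3% of the naive list (1241 of 2245, interval 53.2 to 57.3%) and 55.6% of the IL-4c list (2786 of 5011, interval 54.2 to 57.0%). Most of these lay within 1 kb of the TSS, 49.1% and 49.4% of all peaks. Introns held 438 naive and 951 IL-4c peaks, and distal intergenic regions 22.0% and 19.4%. Exons held 1.87% of the naive peaks (interval 1.35 to 2.52%) and 3.51% of the IL-4c peaks (interval 3.02 to 4.06%). The class of a site could differ between the lists, whose peaks differed in width. Overlapping peaks at Nos2 were called intron in the naive list (480 bp) and exon in the IL-4c list (928 bp). Whether width accounts for the difference in exon shares was not tested. Within 1 kb of either end of a protein-coding gene lay 44.4% of the naive peaks, against a mean of 3.75% and a maximum of 5.08% over 1000 shuffles of the peaks within their chromosomes. For the IL-4c peaks the share was 44.3%, against a shuffled mean of 4.61% and a maximum of 5.95%.

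**Figure D1:**
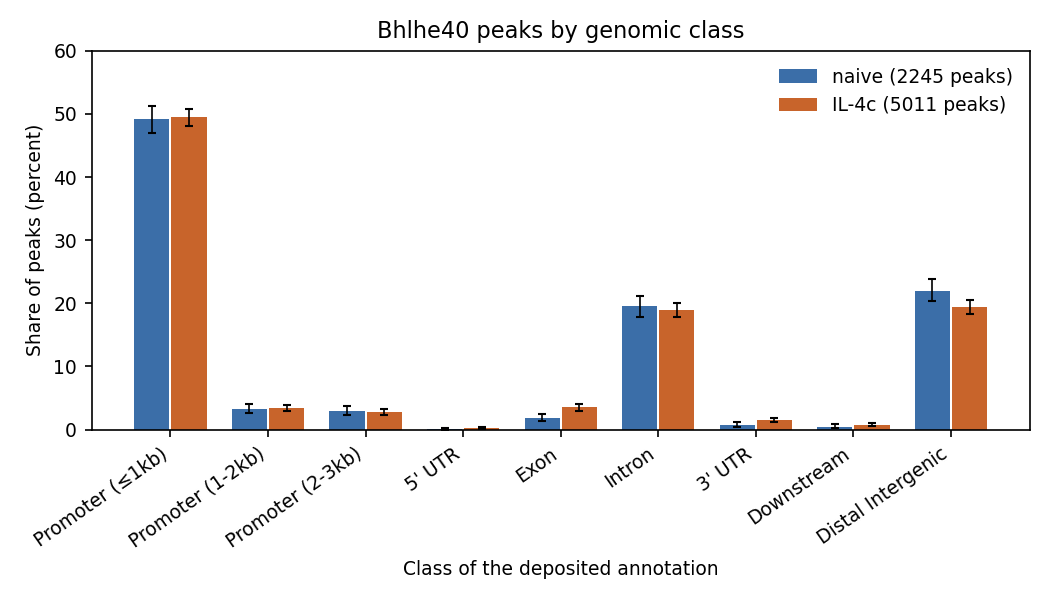
Share of Bhlhe40 peaks (percent, y axis) in each class of the deposited annotation (x axis) in the naive library (blue, 2245 peaks) and the IL-4c library (orange, 5011 peaks). Bars are shares and lines are exact 95% binomial intervals over peaks. The class within 1 kb of a TSS was the largest in both, with 49.1% and 49.4%.

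The second question was how far the same sites were bound in both libraries. Of the naive peaks, 1681 of 2245 (74.9%, interval 73.0 to 76.7%) overlapped an IL-4c peak by at least 1 bp. In the other direction 1647 of 5011 IL-4c peaks (32.9%, interval 31.6 to 34.2%) overlapped a naive peak. Shuffled naive peaks gave a mean of 6.37 overlaps and a maximum of 15, and shuffled IL-4c peaks a mean of 6.14 and a maximum of 16. Where 1 naive peak met 1 IL-4c peak, in 1615 pairs, the summits lay a median of 34 bp apart. The overlap depended strongly on how it was counted, and a required reciprocal overlap of 50% gave 8.55% of the naive and 3.83% of the IL-4c peaks, since the IL-4c peaks were about 3.05 times as wide. With the same number of top peaks from each list the shares were 60.2% and 58.8%, and 49.7% of the IL-4c peaks with a score of at least 100 overlapped a naive peak.

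Among IL-4c peaks with no naive counterpart the highest scores were at promoters of Mllt1, a subunit of the super elongation complex (chromosome 17, 56935173 to 56936289, 169 tags, score 1074), Shisa8 (179 tags, score 957.9), Septin11, a cytoskeletal septin (170 tags, score 948.3), and Mga, a partner of Max (220 tags, score 912.0), and at a site near Sipa1l2 (125 tags, score 838.6). The highest peaks of the naive list with no counterpart in the annotated IL-4c list were 3 sites assigned to Lrrc4c (994, 797 and 307 tags), 1 assigned to Ly6c2 (613 tags) and 1 assigned to Mir101c (379 tags). Their fold enrichments were between 5.06 and 7.96, and all 5 overlapped a peak of the longer IL-4c interval list that its annotated table left out.

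Peaks found in 1 list only were mostly the low scoring ones in the naive list, and less strictly so in the IL-4c list. Of the 3364 IL-4c peaks without a naive counterpart, 1455 had a score of at least 100. Each list was divided by score into 4 groups of equal size. In the highest naive group 548 of 562 peaks overlapped an IL-4c peak (interval 95.9 to 98.6%), and in the lowest 34.9% did (196 of 561, interval 31.0 to 39.0%). In the IL-4c list the share was 78.3% in the highest group (981 of 1253, interval 75.9 to 80.5%) and 8.15% in the lowest (102 of 1252, interval 6.69 to 9.80%).

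**Figure D2:**
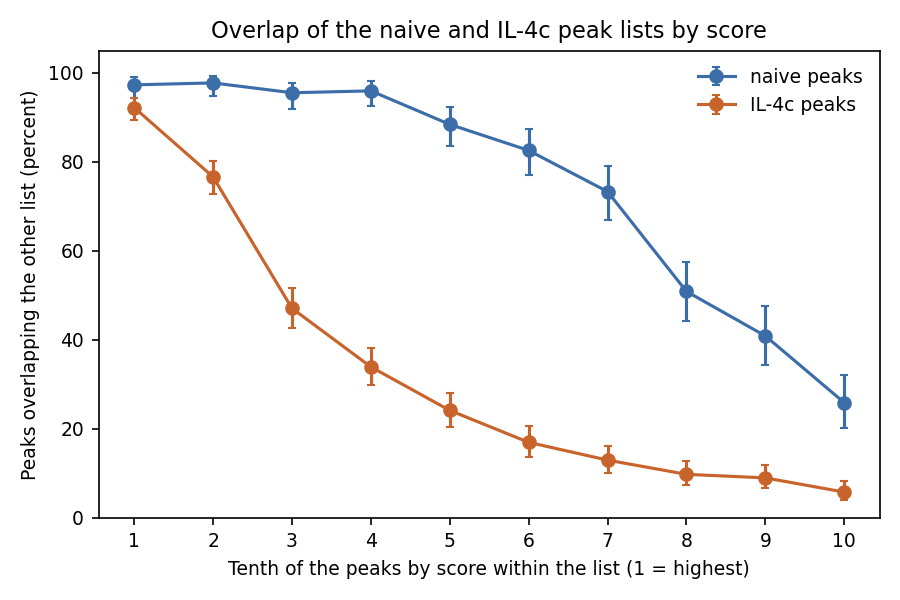
Share of peaks overlapping the other list by at least 1 bp (percent, y axis) in 10 equal groups ranked on the authors' score within each list (x axis, 1 is the highest), for naive peaks (blue) and IL-4c peaks (orange). Points are shares and lines are exact 95% binomial intervals; the share was 97.3% and 92.2% in the highest group and 25.9% and 5.79% in the lowest.

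Shared peaks lay at promoters more often than unshared ones. Among naive peaks 65.1% of the shared (1095 of 1681) and 25.9% of the unshared (146 of 564) were promoter peaks, an odds ratio of 5.35 (Fisher's exact test, two-sided, adjusted p = 8.11e-60). Among IL-4c peaks the shares were 65.6% (1080 of 1647) and 50.7% (1706 of 3364), an odds ratio of 1.85 (Fisher's exact test, two-sided, adjusted p = 1.81e-23). With a required reciprocal overlap of 50% the odds ratio among naive peaks was only 1.57 (Fisher's exact test, two-sided, adjusted p = 0.00754). These tests run over peaks and describe these 2 lists. The promoter share also fell with score, from 67.3% in the highest of the 4 naive groups to 35.8% in the lowest. In the IL-4c list it fell from 65.8% to 44.4%. Score was not held constant in these tests, so that score and sharing were not separated.

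The third question was which genes carried the peaks. Bhlhe40 was bound at its own promoter in both libraries, at 108660105 to 108660503 on chromosome 6 in the naive list (22 tags, score 89.8) and 108658953 to 108660883 in the IL-4c list (226 tags, score 1071). Its paralogue Bhlhe41 had 2 promoter peaks in the naive list (41 and 24 tags), and the same 2 sites (129 and 61 tags) and a further, downstream site (127 tags) in the IL-4c list. Maf, which encodes a large Maf factor that restrains macrophage self-renewal, had a promoter peak (chromosome 8, 115707368 to 115707615, 13 tags in the naive list and 66 in the IL-4c list) and an intergenic peak 199813 bp from its TSS (41 and 121 tags). A further intergenic Maf peak was called in the IL-4c list alone (29 tags). Il10, the gene of an anti-inflammatory cytokine, had an intergenic peak 6017 bp from its TSS on chromosome 1 (11 and 67 tags). Gata6, the identity factor of large peritoneal macrophages, and Myc were assigned no peak in either table.

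At the level of genes, 1846 of 21887 protein-coding genes were assigned a naive peak, 3763 an IL-4c peak and 1479 both, where independent lists would share 317.4. Counting promoter peaks alone gave 1136, 2496 and 985 genes, where independent lists would share 129.6. A gene could be assigned a peak far from its TSS, as for Syt1 in the naive list (-350039 bp). Some genes differed between the tables through the annotation alone. Of the 1615 paired peaks 33 were given different genes, and 24 of the 2284 genes assigned a peak only in the IL-4c table, and 28 of the 367 assigned one only in the naive table, had a peak that overlapped a peak of the other library.

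Clock genes were bound more completely than any other list in the naive library. The random gene lists, here and below, were matched on gene territory and not on expression in macrophages. Whether expressed genes in general were bound above these random lists was not tested. Of 19 clock and PAR-bZIP genes 13 were assigned a peak in the naive list and the same 13 in the IL-4c list (68.4%, interval 43.4 to 87.4%), 7.78 and 3.87 times the mean of random gene lists matched on gene territory (adjusted permutation p = 0.00140 and 8.40e-04 over 21 lists). The bound genes were Ciart (99 and 397 tags), Dbp, a clock-controlled PAR-bZIP factor (59 and 275 tags), Bhlhe40, Bhlhe41, Nr1d1, the gene of the repressor Rev-erb alpha (26 and 197 tags), Nr1d2, Per1, Per2, Cry1, Cry2, Clock, Tef and Hlf. In the naive list 12 of them had a promoter peak and in the IL-4c list all 13 did. Every one of the 13 had a peak overlapping a peak of the other library. Among other bound genes 35.6% had a peak in both tables, and the clock list was the only one of the 21 that differed from the other bound genes in this share (Fisher's exact test, two-sided, adjusted p = 3.23e-05).

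Lysosome and autophagy genes were also bound above chance in both libraries, 17 of 41 in the naive list (5.54 times the random mean, adjusted permutation p = 0.00140) and 24 of 41 in the IL-4c list (3.69 times, adjusted permutation p = 8.40e-04). High peaks lay at promoters of Atp6v1h, a subunit of the vacuolar proton pump (150 and 367 tags), and Lamp1, a lysosomal membrane glycoprotein (88 and 293 tags). Fnip2, a folliculin partner, had its highest naive peak at the promoter (62 tags) and its highest IL-4c peak in an intron (193 tags). For Flcn, which had a naive peak only in the annotation, the site itself was bound in both libraries.

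Of 20 AP-1 and immediate early genes 10 were bound in the naive list (5.80 times the random mean, adjusted permutation p = 0.00140) and 14 in the IL-4c list (3.93 times, adjusted permutation p = 8.40e-04). They included Zfp36 (158 and 414 tags), Atf3, a stress-induced repressor, at an exon -6190 bp from the TSS (86 and 379 tags), Fos at an intergenic site (91 and 155 tags) and Fosb (44 and 129 tags). Among glycolysis and hypoxia genes 8 of 26 and 15 of 26 were bound (3.50 and 3.22 times the random mean, adjusted permutation p = 0.0101 and 8.40e-04). Their highest scores in the IL-4c list were at Bnip3 (148 and 386 tags), Hif1a, the hypoxia factor (35 and 203 tags), Hk1, a hexokinase (9 and 107 tags), and Gpi1 (40 and 108 tags). Among lipid and sterol genes 9 of 22 and 11 of 22 were bound (4.55 and 2.67 times, adjusted permutation p = 0.00210 and 0.00540). These included Acaca, an acetyl-CoA carboxylase (16 and 171 tags), and Srebf1, the sterol-regulated transcription factor (40 and 111 tags).

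Genes of the inflammatory cytokine list were bound in 7 of 25 and 14 of 25 cases (3.18 and 3.13 times the random mean, adjusted permutation p = 0.0252 and 0.00140). The list also holds genes that are not cytokines, such as Nfkbia, Tnfaip3, Relb, Nos2 and Socs3. Its bound cytokine and chemokine genes were Il10, Il6, Ccl2 and Ccl4 in both libraries, and Il12b and Ccl3 in the IL-4c list alone. The highest scores in the IL-4c list were given to Tnfaip3, Nfkbia, Nos2 and Relb. Tnfaip3, an inhibitor of NF-kB signalling, held 62 and 212 tags, and Nfkbia, at an intergenic site 18074 bp from its TSS, 28 and 198 tags. Nos2, the inducible nitric oxide synthase, held 43 and 119 tags, and Relb 85 tags in the IL-4c list alone. With promoter peaks alone 1 of the 25 genes was bound in the naive list and 4 in the IL-4c list (adjusted permutation p = 1 and 0.963). The naive call was also lost with peaks within 50 kb of the TSS (adjusted permutation p = 0.0635) and with a score of at least 100 (adjusted permutation p = 0.0972).

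Of 3 lists above chance in the IL-4c list and not in the naive list, the cell cycle list held 18 of 43 bound genes (2.46 times the random mean, adjusted permutation p = 8.40e-04) against 7 of 43 in the naive list (1.94 times, adjusted permutation p = 0.256). Its highest scores in the IL-4c list were at Aurka, at the site given to Cstf1 in the naive list, Cdkn1c, a cyclin-dependent kinase inhibitor (29 and 137 tags), Cdk4 (28 and 132 tags) and E2f1, in the IL-4c list alone (123 tags). Ribosome biogenesis genes were bound in 8 of 20 cases in the IL-4c list (adjusted permutation p = 0.0315) and 5 of 20 in the naive list (adjusted permutation p = 0.0656), with promoter peaks at Pes1 (133 and 347 tags), Ncl, which encodes nucleolin (48 and 210 tags), Gnl3 (10 and 97 tags) and Fbl (23 and 123 tags). With unmatched random lists the IL-4c call was lost (adjusted permutation p = 0.0681), and with promoter peaks alone the naive list passed (adjusted permutation p = 0.0162). Large Maf and self-renewal genes were bound in 7 of 13 cases in the IL-4c list (adjusted permutation p = 0.0336) and 5 of 13 in the naive list (adjusted permutation p = 0.0618), and included Foxo3, Bhlhe41, Maf and Klf4 (11 and 84 tags). For this list the IL-4c call was lost with peaks within 50 kb of the TSS and with a score of at least 100 (adjusted permutation p = 0.0728 and 0.0672). The naive list passed with unmatched random lists, promoter peaks alone and peaks within 50 kb (adjusted permutation p = 0.0210, 0.00210 and 0.0175). The plan also covered genes bound in either library and genes with a shared peak. For these sets, in that order, adjusted permutation p was 7.00e-04 and 0.101 for cell cycle and 0.0630 and 0.0288 for ribosome biogenesis. For large Maf and self-renewal it was 0.0817 and 0.0719. For these 3 lists the difference between the libraries in excess over the random lists was not tested. Their share of genes bound in both did not pass the threshold against other bound genes. Adjusted p was 0.949 for cell cycle, 0.474 for ribosome biogenesis and 0.444 for large Maf and self-renewal (Fisher's exact test, two-sided). The 3 lists were thus not shown to differ between the libraries.

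**Figure D3:**
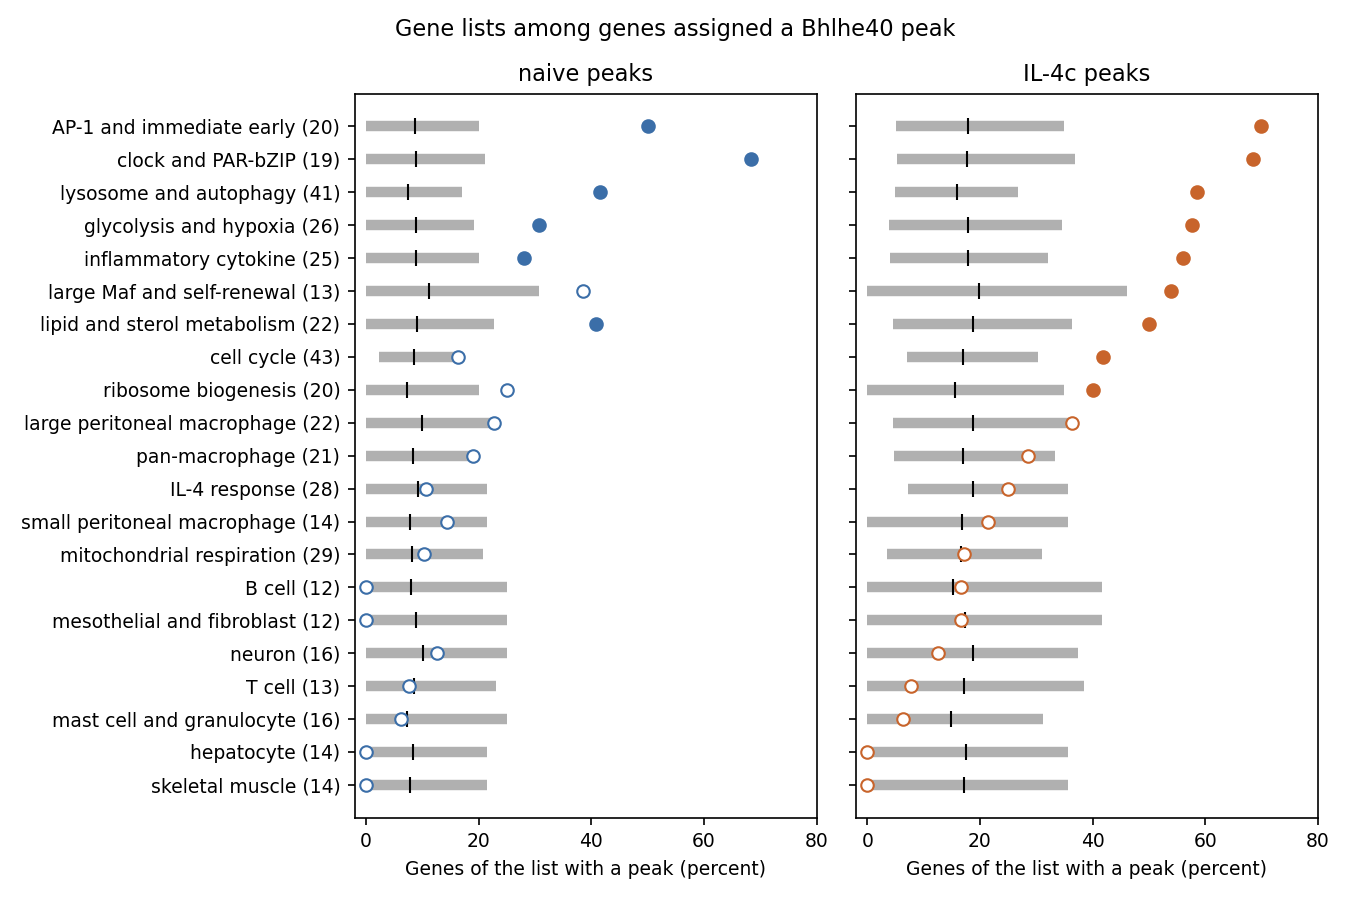
Genes with a Bhlhe40 peak as a share of each gene list (percent, x axis; number of genes in brackets) in the naive (left) and IL-4c (right) library. Filled points passed an adjusted p of 0.05 and open points did not, grey bars span the middle 95% of 10000 matched random lists and ticks mark their mean; 6 lists lay above chance in the naive library and 9 in the IL-4c library.

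Genes of the IL-4 response did not pass the threshold in either library. In the naive list 3 of 28 were bound (1.17 times the random mean, adjusted permutation p = 1). In the IL-4c list 7 of 28 were bound (1.33 times, adjusted permutation p = 0.785). Simulated lists of 20 genes bound at 2 times chance were recovered in 2% of cases. An excess of that size could thus be missed, here and in the next paragraph. Kdm6b, a histone demethylase, was bound in both (60 and 321 tags). Chil3, a chitinase-like protein of alternatively activated macrophages (10 tags), and Tgm2 (10 tags) had a peak in the naive list alone. Ccnd2, a D-type cyclin (59 tags), Clec10a, a C-type lectin (67 tags), Batf3 (65 tags), Socs1, a suppressor of cytokine signalling (61 tags), and Ccl24, an eotaxin (43 tags), had a peak in the IL-4c list alone.

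Identity genes of large peritoneal macrophages were bound in 5 of 22 and 8 of 22 cases (2.29 and 1.94 times the random mean, adjusted permutation p = 0.256 and 0.165). They included Cebpb, a regulator of these cells (73 and 115 tags), F10, a coagulation factor (17 and 134 tags), and, in the IL-4c list alone, Icam2 (74 tags) and Tgfb2 (61 tags). Pan-macrophage genes were bound in 4 of 21 and 6 of 21 cases (adjusted permutation p = 0.320 and 0.404), among them Adgre1, which encodes F4/80, at an intergenic site (58 and 55 tags), Cebpa at different sites in the 2 lists (15 and 34 tags) and Ptprc in the IL-4c list alone (59 tags). Small peritoneal macrophage genes were bound in 2 of 14 and 3 of 14 cases (adjusted permutation p = 0.926 and 0.991), namely Cd74, the invariant chain (33 and 118 tags), Ciita, the class II transactivator (12 and 64 tags), and H2-Aa in the IL-4c list alone (38 tags). Mitochondrial respiration genes were bound in 3 of 29 and 5 of 29 cases (adjusted permutation p = 1 in both). Cycs, the cytochrome c gene, was assigned an intergenic peak 20631 bp from its TSS (102 and 279 tags). Peaks also lay at Nrf1 (44 and 69 tags), Atp5a1 at different sites in the 2 lists (10 and 57 tags) and Sdha in the IL-4c list alone (49 tags).

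No list of other cell types passed the threshold. At these sizes the test had little room to show binding below chance. The random mean was 0.951 for the B cell list in the naive library and 2.45 for the hepatocyte list in the IL-4c library, where 0 genes were bound. B cell genes were bound in 0 of 12 and 2 of 12 cases (Ebf1, 31 tags, and Ms4a1, 22 tags, both in the IL-4c list; adjusted permutation p = 0.976 and 1), and T cell genes in 1 of 13 in each library (Cd28, at different sites, 9 and 22 tags; adjusted permutation p = 1 and 0.829). Mast cell and granulocyte genes were bound in 1 of 16 in each library (Csf3r, at different sites, 16 and 26 tags; adjusted permutation p = 1 and 0.800), and mesothelial and fibroblast genes in 0 of 12 and 2 of 12 (Upk3b, 39 tags, and Krt8, 35 tags; adjusted permutation p = 0.926 and 1). Neuron genes were bound in 2 of 16 in each library (Camk2a, 42 and 134 tags, with Syt1 in the naive list, 9 tags, and Gad1 in the IL-4c list, 25 tags; adjusted permutation p = 1 and 0.973). Of the hepatocyte and skeletal muscle lists, 0 of 14 genes each were bound in either library (adjusted permutation p = 0.926 in the naive list and 0.253 in the IL-4c list). In simulated lists of 20 genes this test found 2% of those bound at 2 times chance and 100% at 4 times. Binding below chance was not simulated.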

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

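The tests of background and of threshold effects in this part were chosen only after the results were seen. The interval lists held peaks that the annotated tables left out, and they enter the comparisons above only where the 5 highest unshared naive peaks were set against the longer IL-4c interval list. There were 64 such peaks in the naive library, of which 34 overlapped a peak of the IL-4c interval list, and 288 in the IL-4c library, of which 33 overlapped a peak of the naive interval list. On the unplaced contig JH584304 the naive interval list had 10 peaks and the IL-4c list 5.

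Of the naive peaks, 564 had no counterpart in the annotated IL-4c table. In the alternative with every interval-list peak, 26 of the 564 overlapped a peak of the IL-4c interval list. High-background regions such as those at Lrrc4c and Mir101c were not shown to be the source of most of the 564. Of these peaks 8.69% (49 of 564, interval 6.50 to 11.3%) had a fold below 8. Weak peaks may pass the caller only at a higher fold, so that this share cannot decide the question. Among the 564, Cd28 with 9 tags had a fold of 8.81 and Cebpa with 15 tags a fold of 7.53. The share below 8 among all naive peaks is not given here. False positives at the caller's own rate are too few to account for the 564, since that rate allows 8.98 peaks in the whole naive table. Whether that rate holds for these peaks was not tested. Weak calls in the naive library stay open. Of these peaks 90.1% (508 of 564, interval 87.3 to 92.4%) lay below the median naive score of 87.1, but this repeats the fall of overlap with score given above and is no separate test. Loss of binding after IL-4c stays open and was not tested, because there was 1 library per condition.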

How the results depend on the processing

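All alternatives described here were planned, except the use of every interval-list peak and the overlap-based count of genes bound in both, which were chosen after the data were seen. A score of at least 100 left 985 naive and 2895 IL-4c peaks, raised the promoter share to 65.6% and 61.0%, and left 862 naive and 2364 IL-4c genes, 799 in both, or 607, 1623 and 560 with promoter peaks. The smaller counts follow from the stricter threshold. A promoter limit of 1 kb gave 49.1% and 49.4%, and the same number of top peaks gave 62.8% for the IL-4c list. The overlap of the lists moved most. Reciprocal overlap of 50% gave 8.55% of naive and 3.83% of IL-4c peaks, as the difference in width requires, and summits within 200 bp gave 71.8% of naive peaks. A score of at least 100 in both lists gave 91.9% and 30.9%, and in the counted list alone 96.1% and 49.7%. The same number of top peaks per list gave 60.2% and 58.8%; the cause was not tested.

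Promoter odds ratios of shared against unshared peaks stayed above 1 and past the threshold in both lists, but with a reciprocal overlap of 50% they were 1.57 (naive) and 1.51 (IL-4c). The clock list stayed the only one past the threshold when its share of genes bound in both libraries was set against that of other bound genes. Of 168 alternative values for single gene lists 146 kept their direction against the random mean and their side of the threshold, 6 lost the threshold, 4 gained it and 12 reversed. The only reversal of a list past the threshold was the inflammatory cytokine list in the naive library with promoter peaks alone, at 4% of its genes, because 1 of its 7 bound genes had a promoter peak. The other 11 reversals were of lists past the threshold in neither setting. With promoter peaks alone they were the naive IL-4 response (3.57% of genes bound) and neuron lists (0%) and the IL-4c pan-macrophage (9.52%) and B cell lists (0%). With peaks within 50 kb of the TSS they were the naive T cell (7.69%) and neuron lists (6.25%) and the IL-4c B cell (8.33%) and mesothelial and fibroblast lists (16.7%). With a score of at least 100 they were the naive IL-4 response (3.57%) and IL-4c B cell lists (8.33%), and with unmatched random lists the IL-4c B cell list (16.7%). The cause of these 11 was not tested. Restriction to chromosomes 1 to 19, X and Y removed no peak from the tables. Alternatives of the motif and E-box analyses were not run. No paired analysis was possible because each condition had 1 ChIP library. The weakest peaks held 9 tags in the naive and 17 in the IL-4c table.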

Other observations

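Except for the matched test of the clock list and the comparison of sites inside and outside promoters, the tests in this part were chosen only after the results were seen. Protein-coding genes were grouped by the letters that open their symbols into 259 families of at least 10 genes. The families and genes named here were chosen after their values were seen. In the IL-4c library 9 families were bound above matched random lists, and in the naive library 0 were. The difference between the libraries was not tested, and in the naive list the 9 families were bound at 0.873 (Arhgef) to 4.51 (Klf) times the random mean. A shared prefix is not a shared function, and Atp and Map in particular mix unrelated genes. The Kruppel-like factor genes led by ratio to chance after the autophagy genes, with 11 of 17 Klf genes bound (64.7%, 3.38 times the random mean, adjusted permutation p = 0.0173), among them Klf11 (highest score 699.4), Klf15 (631.9) and Klf3 (510.8). In the naive list 8 of the 17 Klf genes were bound (adjusted permutation p = 0.0691). Autophagy genes of the Atg family were bound in 11 of 18 cases (3.64 times, adjusted permutation p = 0.0173), with the highest peak at Atg4c (score 2718). The other families above chance were Dusp, dual specificity phosphatases, with 12 of 24, Zbtb with 17 of 41, Cdk with 12 of 26, Arhgef with 12 of 25, Arhgap with 15 of 34, Map with 19 of 47, and Atp with 28 of 85, where Atp6v1h, a proton pump subunit, had the highest score (2653).

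Some families were almost free of peaks. Olfactory receptor genes (Olfr) were bound in 3 of 1110 cases in the naive library and 4 of 1110 in the IL-4c library (adjusted permutation p = 0.0259 and 0.0173), and vomeronasal receptor genes (Vmn) in 2 of 355 and 1 of 355 (adjusted permutation p = 0.0259 and 0.0173). Krtap, Pramel and Scgb genes were bound in 0 of 56, 0 of 47 and 0 of 40 cases in the IL-4c library.

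Over 1615 paired sites the median ratio of IL-4c to naive tags was 3.55 (bootstrap interval 3.44 to 3.61). Deeper sequencing of the IL-4c library could account for it, and 5 pairs of high local background had a median ratio of 1.53 (interval 1.05 to 3.23), too few to decide. High local background meant a fold below 8 in both libraries, at least 60 naive tags and under 0.5 naive tags per bp. Wider peak windows are another candidate explanation, since the median ratio of tags per kb was only 1.20 (interval 1.17 to 1.23), between the bounds set for either outcome. A difference in yield and a difference between the conditions cannot be told apart with 1 ChIP library per condition.

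Among paired sites Bhlhe40 stood out in raw tags at its own promoter, where the ratio was 10.3 (22 and 226 tags, counting interval 6.62 to 16.7). This was higher than at 98.8% of the pairs, and higher than at 99.7% of the pairs in the same of 5 groups by naive tags. The IL-4c peak there was also wider (1931 bp against 399 bp), and the ratio of tags per kb was 2.12. That was above the median of 1.20 over all pairs, but other sites had higher ratios of tags per kb. These included Nr1d1 (2.20) and Tbcel (2.84), and the highest was 3.64. The rank of Bhlhe40 in tags per kb is not given here. Over its 13 bound genes the clock list had a median ratio of raw tags of 4.64. Of random sets of as many pairs 0.66% lay above it once the naive tag count was allowed for. For ribosome biogenesis genes the median was 5.35 with 2.48% of random sets above, and for lysosome and autophagy genes 3.79 with 3.23% above. In the other 6 of the 9 lists examined between 29.0% (glycolysis and hypoxia) and 70.2% (lipid and sterol metabolism) of random sets lay above. These values were not adjusted for the number of lists.

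Peaks at all 13 bound clock genes in both libraries may reflect a set of sites bound in either state, which is a hypothesis from these 2 libraries. That strong peaks are found in both libraries whatever their gene stays open as the whole cause. The list lay at the 99.0th percentile of random bound genes matched on score, which had a mean of 10.1 genes in both. In 1.95% of the random lists all 13 genes were bound in both. The clock list was already the only one of 21 lists past the threshold on its share of genes bound in both. The matched test used the same 2 libraries and was not adjusted for the choice of this list, so that it cannot decide the question. Reproducibility of the clock gene sites in further libraries, and motifs at them, were not tested.

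A few sites held no more tags in the IL-4c library than in the naive library. Pairs with at least 30 naive tags numbered 603, without predicted genes and high-background sites as defined above. Their lowest ratios were at Xxylt1 (0.857, 42 and 36 tags), Gas7 (0.913), Adgre1 (0.948, 58 and 55 tags), Setd1a (39 and 39 tags), Nisch (1.01) and Actb (1.02). The highest were at Mfsd1 (9.06), Mir6944 (8.13) and Mthfd1l (8.11). The 10 lowest also held Pak3 (110 and 115 tags, folds of 5.68 and 6.58), which only the limit on tags per bp kept among the 603. With predicted genes included, the median ratio of 198 pairs outside promoters was 2.66 (interval 2.46 to 2.84), below the 3.06 of 437 promoter pairs (interval 2.88 to 3.19), while promoters held 5 of the 10 lowest and 7 of the 10 highest of the 603 sites, against 69.8% of all 603.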
